A study of Mus musculus with 8 samples.

How the data were processed

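RNA was isolated from cultured primary mouse brain microvascular endothelial cells with a column kit, and libraries were made with an NEBNext Ultra RNA kit, per the labels' protocols. The cells were grown in DMEM with fetal calf serum, fibroblast growth factor and heparin. The 4 wild type and 4 Cavβ3-deficient libraries were assigned to groups from their titles, which also give the replicate numbers. Reads were aligned with HISAT2 version 2.0.5, per the submitters' processing notes. The counting tool, genome build, annotation, filters and use of strand are not given in the sources used here. The deposited values are FPKM, 1 table per library with 54532 Ensembl genes, and no libraries were pooled by the authors in these tables.

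Gene symbols were found for 54409 of the identifiers in a table of gene names. Each FPKM value multiplied by the gene's exon length in GENCODE M21 (GRCm38), available for 54495 genes, came out as a whole multiple of a constant per library for 96.2% to 96.8% of the values above 0, within a tolerance of 0.01. This constant gave the implied depth of 23491645 to 33813060 reads or fragments and recovered reads per gene. Coordinates are those of GENCODE M21. A gene with 0 recovered reads was given an upper limit of 3 reads, and such limits cover counting error only. The 8 housekeeping genes checked were above 0 in every library, and no pair of libraries held identical values.

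FPKM values are not counts, so genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with intensity trend and robust variance moderation, for 11864 genes with an FPKM of at least 1 in at least 4 libraries. Fold changes on this scale understate the change of genes with low FPKM. The plan held a branch for count tables, which was not needed. All 8 libraries entered the fit, without covariates, and a gene passed at a Benjamini-Hochberg adjusted p of 0.05. The 49 gene lists, 34 of pathways and complexes, 12 of cell type markers and 3 technical, were fixed before the data were examined, and 37 of them with at least 5 tested members were tested with camera at a preset correlation of 0.01. The result of 1 called pathway list is not reported here on its own, although the counts of lists include it. Estimated correlations and fry were run as alternatives. Camera compares a list with all other genes, while fry asks whether the list's genes move in 1 direction. Single values were compared with exact two-sided permutation tests over 70 splits, and calls near Cacnb3 with Fisher's exact test.

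The rule for named genes was also fixed in advance. It took Cacnb3, the 12 risen and 12 fallen called genes with the largest fold changes whose groups did not overlap and whose mean FPKM was at least 1, without provisional symbols. It added up to 4 called members of each list, a fixed set of barrier and calcium genes, sex-linked genes and up to 5 called genes nearest to Cacnb3. The planned comparison called no gene, so the rule was applied to the fit with the library batch as a term. That fit, and every other use of the batch, was chosen after Y-linked transcripts had been seen in replicates 1 and 2 only, and it was one of several fits tried. The batch was inferred from the data and not from the labels.

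Libraries with the same replicate number deviated together from their group means, with correlations across genes of 0.41, 0.75, 0.40 and 0.52. By the criterion set for pairing, a correlation above 0.1 in every pair, the numbers pair the libraries, and the fit with the replicate number as a block is given where it changed a call. Within batches the replicate differences of the 2 groups correlated at 0.19 and -0.35, so the pairing follows the batch more than the single number.

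The alternatives tried were quantile normalization, median centring, no filter, a filter at an FPKM of 5, limma without trend, array weights, a pseudocount of 0.1, the replicate block, leaving out X and Y genes, leaving out each library, limma-voom on recovered reads and removal of each library's GC trend by loess. The limma fits with and without the batch term, and camera with the batch term, were tested on simulated data with known changes drawn for the same 11864 genes. For log2 fold changes of 0.5, 1 and 2, the planned fit recovered 34%, 77% and 98% of the changed genes, with 1 false call, and the fit with the batch term recovered 70%, 93% and 100%, with 7 false calls. The changed genes were drawn from those with a fitted log2(FPKM + 1) above 2, so these shares do not cover lower genes. Noise was drawn independently for each gene, so the check of camera held no correlation between genes. Permutation tests were run in R. Data preparation, exon overlaps and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.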

Results

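RNA sequencing was carried out on primary mouse brain microvascular endothelial cells, the cells that line the brain's small vessels and form the blood-brain barrier. The 8 libraries comprised 4 labelled wild type and 4 labelled as deficient in Cavβ3, an auxiliary β subunit of voltage-gated calcium channels encoded by Cacnb3. The labels describe the 4 libraries of each genotype as independent biological replicates. Each library was deposited as FPKM values for 54532 Ensembl genes. The steps between low FPKM values implied depths of 24946875 to 28475510 assigned reads or fragments in the wild type libraries and of 23491645 to 33813060 in the libraries labelled Cavb3 knockout. An FPKM of at least 1 was reached in at least 4 libraries by 11864 genes, which were tested. The design asks how Cavβ3 bears on endothelial function, so the genotypes were compared gene by gene and by gene lists chosen before the data were examined.

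The targeted gene itself did not separate the labels. Cacnb3 (ENSMUSG00000003352, protein coding, chromosome 15, 98630840 to 98644529, plus strand, GRCm38) stood at 3.38, 3.56, 1.12 and 0.980 FPKM in wild type replicates 1 to 4. In the libraries labelled Cavb3 knockout it stood at 1.70, 2.09, 2.47 and 1.77 FPKM. The means were 2.26 ± 1.40 and 2.01 ± 0.352 FPKM (SD, n = 4 each), a ratio of 0.888, and a two-sided exact permutation test over the 70 splits gave p = 0.943. The limma estimate was -0.02 on the log2(FPKM + 1) scale (95% confidence interval -0.69 to 0.66, adjusted p = 0.996). Within replicates 1 and 2 the ratio was 0.546 (log2 difference -0.63), and within replicates 3 and 4 it was 2.02 (log2 difference 0.60). The recovered reads on Cacnb3 numbered 102 to 369 per library, so expression was measurable in every library. The gene totals cover all exons and do not show which of them a targeted allele had lost. The group is therefore named by its label only, and each direction given between the groups rests on that label. Of the other channel subunit genes in the fixed list, Cacna1a, Cacna1e and Cacng7 were expressed enough to be tested, and none passed (log2 differences -0.15, 0.11 and 0.44, limma adjusted p of 0.954, 0.989 and 0.928). Among those too low to test, Cacna1c, picked after its values were seen, was at 0.372 ± 0.0653 FPKM in wild type. It was at 0.826 ± 0.425 FPKM in the libraries labelled Cavb3 knockout (SD, n = 4 each), without overlap.

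**Figure D1:**
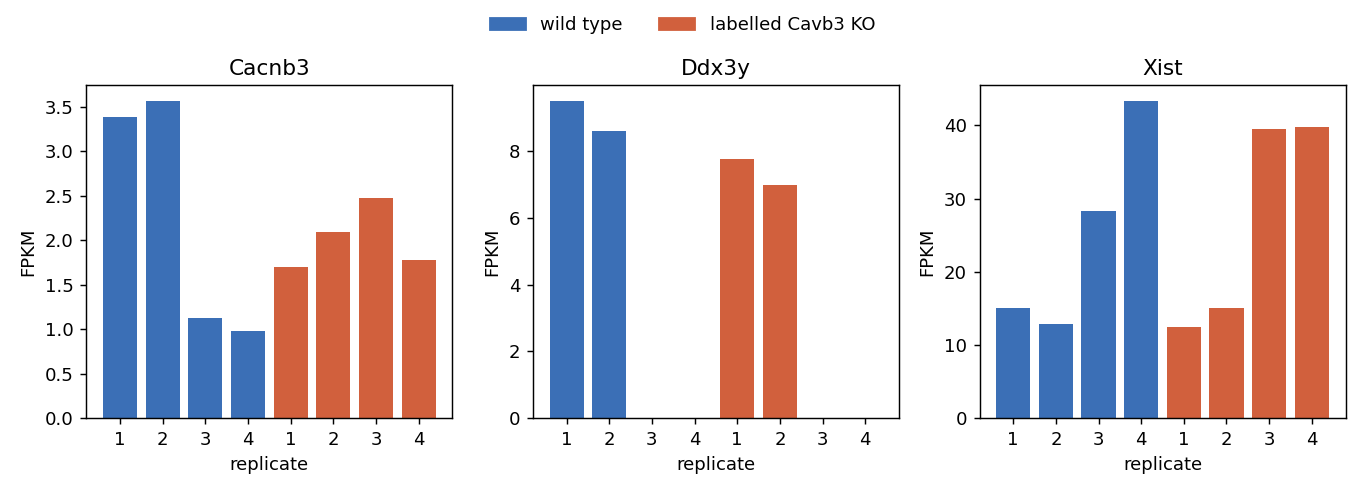
Expression (FPKM, y axis) of Cacnb3, Y-linked Ddx3y and Xist in each of the 8 libraries (x axis, replicate number), with wild type in blue and the libraries labelled Cavb3 knockout in orange; each bar is 1 library. Cacnb3 lies between 0.980 and 3.56 FPKM with overlapping groups, and Ddx3y is at 0 in replicates 3 and 4 of both groups.

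Replicates 1 and 2 of both groups stood apart from replicates 3 and 4. The Y-linked gene Ddx3y, an RNA helicase, was at 9.48, 8.59, 7.76 and 6.98 FPKM in the 4 libraries of replicates 1 and 2, and Uty, Kdm5d and Eif2s3y were likewise detected there. No read of these 4 genes was recovered in replicates 3 and 4 of either group, which allows at most 0.0246 FPKM of Ddx3y (3 reads; counting error only). Xist, transcribed from the inactive X chromosome, was at 12.4 to 15.1 FPKM in replicates 1 and 2 and at 28.3 to 43.3 FPKM in replicates 3 and 4. The first principal component of the 500 most variable genes held 66.0% of the variance and separated these sets of libraries. The second held 10.8%. The third held 7.64% and separated the labelled genotypes, with wild type at 2.37 to 7.97 and the libraries labelled Cavb3 knockout at -5.65 to -3.99. Across genes, the median Pearson correlation was 0.987 between libraries of the same genotype and set, 0.981 between genotypes within a set and 0.957 between sets within a genotype. These sets are called library batches here, although the labels name no batch. With genotype in the limma fit, 5419 of 11864 genes differed between the batches, 2354 higher and 3065 lower in replicates 3 and 4.

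**Figure D2:**
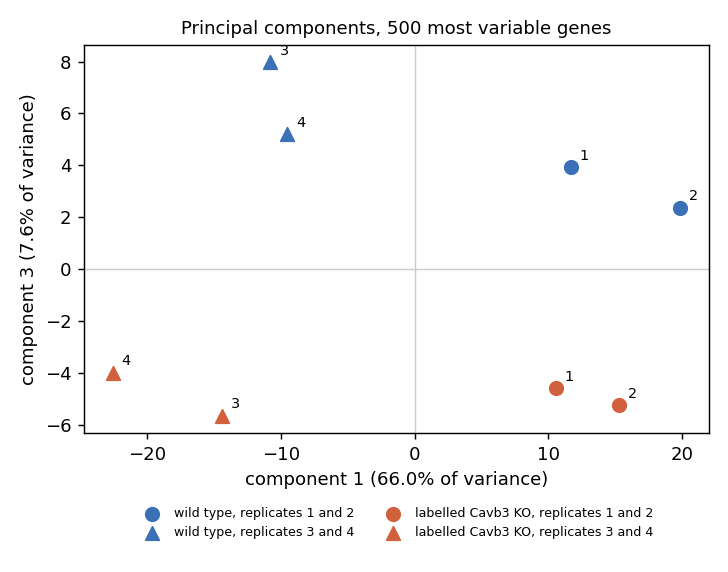
Scores of the 8 libraries on principal components 1 (x axis, 66.0% of variance) and 3 (y axis, 7.64% of variance) of the 500 most variable genes, with circles for replicates 1 and 2, triangles for replicates 3 and 4, blue for wild type and orange for the libraries labelled Cavb3 knockout. Component 1 separates the replicate sets and component 3 the labelled genotypes.

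Between the labelled genotypes, Krt19, an intermediate filament keratin of epithelia, had the largest fold change among the genes named by the rule fixed for this text. Its level was 30.7 ± 5.62 FPKM in wild type and 72.9 ± 14.1 FPKM in the libraries labelled Cavb3 knockout (SD, n = 4 each), with no overlap between groups. Pkd1, which encodes the membrane protein polycystin-1, lay the other way at 28.6 ± 0.940 and 19.6 ± 2.13 FPKM, also without overlap. In the comparison planned without any batch term, neither these nor any other gene passed limma's adjusted threshold of 0.05 (0 of 11864, smallest adjusted p = 0.179). An unadjusted p under 0.05 was reached by 647 genes, 260 higher and 387 lower, and limma-voom on the recovered reads also called 0. Groups that did not overlap were seen for 491 genes, or 4.14%. The share by chance would be 2.86% if all splits of the libraries were equally likely, which ignores the batches.

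With the library batch added as a term, a fit chosen after the batches had been seen, 31 genes rose and 44 fell in the libraries labelled Cavb3 knockout. The genes that rose with no overlap between groups were led by Krt19 (log2 fold change 1.22 ± 0.16 SE), Atp1b1 (1.13 ± 0.17), a β subunit of the sodium-potassium pump, and Twist1 (1.07 ± 0.10), a transcription factor of mesenchymal cells. Slc6a12, a betaine and GABA transporter, rose by 1.05 ± 0.17 and Vnn1, a pantetheinase, by 0.94 ± 0.12. The rule also named Ddit4l, Cntnap5c, Rfk, Fbxo44, Fam213a, Hsf2 and Prrg4, which rose by 0.59 to 0.90. Among the genes that fell, Vash1, a regulator of angiogenesis, had a log2 fold change of -0.74 ± 0.10, from 8.11 ± 1.72 to 4.52 ± 1.39 FPKM (SD, n = 4 each). Sema3f, a secreted guidance protein, followed at -0.61 ± 0.10, Adgrl4, an endothelial adhesion receptor, at -0.58 ± 0.08 and Evl, an actin regulator, at -0.55 ± 0.08. The others named were Pkd1, Rassf3, Ctla2a, Meox1, Notch4, Mcph1, Wfdc2 and Efnb2, at -0.53 to -0.43. The limma adjusted p-values of these 24 genes lay between 0.0404 and 0.0477. Each had the same direction in both batches, which the rule's demand for groups without overlap fixed in advance. In place of 75 calls there were 0 with the replicate number as a block (smallest limma adjusted p = 0.0902), 0 when any 1 wild type library or replicate 1 or 2 labelled Cavb3 knockout was left out, and 322 when replicate 3 labelled Cavb3 knockout was left out. Fitted alone, replicates 1 and 2 gave 0 calls and replicates 3 and 4 gave 6.

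**Figure D3:**
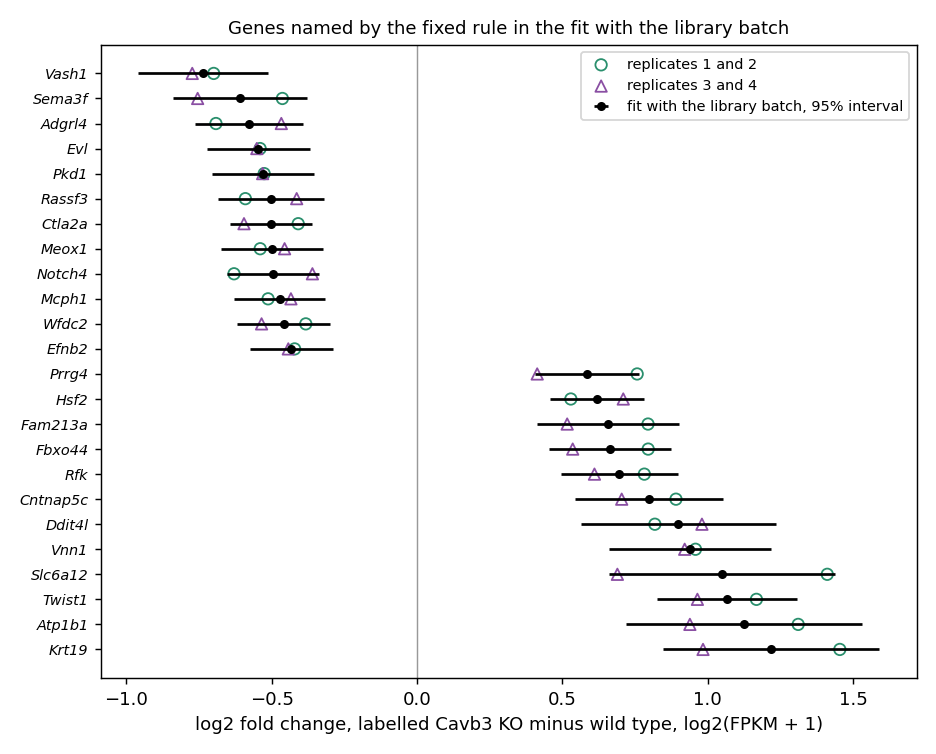
Log2 fold change on the log2(FPKM + 1) scale (x axis, libraries labelled Cavb3 knockout minus wild type) of the 24 genes named by the fixed rule (y axis) in the fit with the library batch; black points with bars give the estimate and its 95% confidence interval, green circles replicates 1 and 2, and purple triangles replicates 3 and 4. The estimates run from -0.74 for Vash1 to 1.22 for Krt19. Both batches lie on the same side of 0 for each gene, which the rule's demand for groups without overlap fixed in advance.

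Genes that mark endothelial cells were lower together in the libraries labelled Cavb3 knockout. All 32 measured members of the fixed endothelial identity list had a negative log2 fold change, with a median of -0.28 over all libraries, -0.32 within replicates 1 and 2 and -0.23 within replicates 3 and 4. With the batch term, 5 of the 32 fell and 27 did not pass. They were Esam, an adhesion molecule of endothelial junctions (-0.38 ± 0.05 SE), Clec14a (-0.37 ± 0.05), Mmrn2 (-0.37 ± 0.05), She (-0.64 ± 0.10) and Icam2 (-0.30 ± 0.05). Of these, Esam, Mmrn2, She and Icam2 overlapped between groups over all 8 libraries. Adjusted over the list alone, 19 fell with the batch term and 0 in the planned comparison. Limma's camera test with its preset correlation gave an adjusted p of 2.29e-10. It was not called with an estimated correlation (adjusted p = 0.519), and the fry test gave an adjusted p of 0.148 without and 0.00306 with the batch term. Marker sums of choroid plexus and ependymal cells (log2 difference 1.35) and of fibroblasts and meninges (0.48) were higher in the libraries labelled Cavb3 knockout. Each had a higher mean in both batches, although neither passed after adjustment (exact permutation adjusted p = 0.186 for both). For fibroblasts and meninges, the higher mean in replicates 3 and 4 rested on replicate 3 labelled Cavb3 knockout.

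Lists of vessel growth and signalling were lower as well. Tip cell genes, active at the front of growing vessels, had a median log2 fold change of -0.46 over 23 members, and 2 of them fell with the batch term, Igfbp3 (-0.92 ± 0.12 SE) and Angpt2, a ligand of the Tie receptors (-0.58 ± 0.08, from 602 ± 122 to 406 ± 104 FPKM, SD, n = 4 each). The Notch list had a median of -0.35 over 15 members and 2 that fell, the receptor Notch4 (-0.49 ± 0.07) and Efnb2 (-0.43 ± 0.06), which is also in the lists of axon guidance molecules and arterial markers. Caveolar and transcytosis genes had a median of -0.25 over 13 members, of which Cav1, the main caveolar coat protein (-0.67 ± 0.10), and Ehd2 (-0.38 ± 0.06) fell. In the basement membrane and matrix list (median -0.30, 29 members) Col18a1 fell (-0.80 ± 0.10), in the TGF-β and BMP list (-0.25, 28 members) the receptor Acvrl1 fell (-0.35 ± 0.06), and in the integrin and focal adhesion list (-0.12, 22 members) Itga4 fell (-0.66 ± 0.10). Axon guidance molecules (-0.22, 25 members, Sema3f and Efnb2 fell), Wnt targets of brain endothelium (-0.22, 17 members, 0 fell) and interferon response genes (-0.24, 26 members, 0 fell) were also called lower. With the preset correlation, camera's adjusted p for these 9 lists lay between 2.44e-06 and 0.0340, and with an estimated correlation the adjusted p was 0.519 or 0.641, so that none was called. Within replicates 1 and 2 alone, the Notch list (median -0.10) and the TGF-β and BMP list (-0.09) were not called (camera adjusted p = 0.122 for both), while in replicates 3 and 4 alone both were, with medians of -0.49 and -0.35. Interferon response genes were called in replicates 1 and 2 (median -0.33) and not in replicates 3 and 4 (-0.11, camera adjusted p = 0.101). These differences between the batches were not tested. The other 6 lists were called in each batch, with medians of -0.46 to -0.16 in replicates 1 and 2 and of -0.38 to -0.12 in replicates 3 and 4. Adjusted over the list alone, the batch term gave 15 tip cell, 7 Notch, 7 caveolar, 14 basement membrane, 8 TGF-β and BMP, 8 focal adhesion, 11 axon guidance, 4 Wnt and 11 interferon genes that fell, and 1 basement membrane gene that rose. The planned comparison gave 4 Notch, 4 caveolar and 1 axon guidance gene that fell, and 0 in the other 6 of these 9 lists. Igfbp3, Cav1, Col18a1, Acvrl1, Itga4 and Angpt2 overlapped between groups over all 8 libraries. Tip cell, axon guidance, focal adhesion and endothelial identity genes were also lower in replicates 3 and 4 than in replicates 1 and 2 (medians -0.54, -0.23, -0.24 and -0.36).

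In all, camera called 16 of 33 pathway lists in the planned comparison, 13 lower and 3 higher. The 3 higher lists shifted little, with medians of 0.04 for ribosomal proteins, 0.08 for sterol and lipid synthesis and 0.06 for the cell cycle, and none of their members passed. Within replicates 3 and 4 alone none of these 3 was called (medians 0.02, 0.00 and 0.05, camera adjusted p of 0.207, 0.896 and 0.622), while replicates 1 and 2 gave 0.07, 0.20 and 0.15 with each list called. None of these 16 lists was called with an estimated correlation (adjusted p of 0.519 or more) or with fry. Fry called 11 of the 33 lists lower with the batch term and 5 with the replicate number as a block, complement and coagulation genes among them both times (median -0.04). Matrix proteases and their inhibitors (median -0.09) were called lower with the replicate number as a block (camera adjusted p = 0.0423, adjusted p = 0.694 with an estimated correlation) and not in the planned comparison (0.108). Some lists outside the 16 were called in 1 batch alone, and whether the batches differed was not tested. In replicates 1 and 2, antigen presentation genes (median -0.29, camera adjusted p = 5.7e-04) and chemokines and cytokines (-0.34, 0.0343) were called lower and hypoxia and glycolysis genes (0.13, 0.00392) higher, with medians of 0.09, 0.06 and -0.15 in replicates 3 and 4. Growth factor genes were called lower in replicates 3 and 4 (-0.26, 0.00953; 0.14 in replicates 1 and 2), as were matrix proteases (-0.16, 0.0321; -0.10 in replicates 1 and 2). With an estimated correlation camera called 0 of 37 lists in either batch alone (adjusted p of at least 0.566 and 0.816). For lists of hypoxia, apoptosis, endothelial to mesenchymal transition, growth factor and NF-κB genes, none of them called over all libraries, the camera direction was up while the median was negative. The unfolded protein list, also not called there, had a median of 0.00 and a mean of -0.02 with an upward camera direction. In lists that were not called or too small to test, single members passed with the batch term: Alcam (0.45 ± 0.06 SE) and Pfkp (0.41 ± 0.06) rose, and Mgst1 (-0.50 ± 0.08) and Stab1 (-0.36 ± 0.05) fell.

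**Figure D4:**
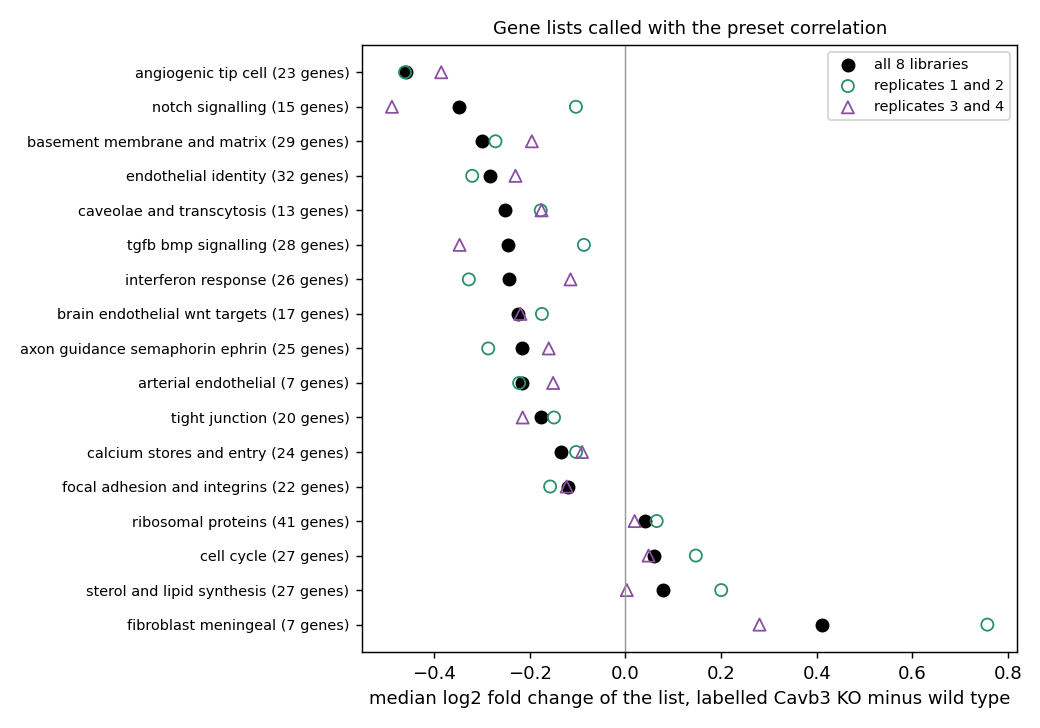
Median log2 fold change (x axis, libraries labelled Cavb3 knockout minus wild type) of the gene lists described here that camera called with the preset correlation (y axis, with the number of tested genes); black points use all 8 libraries, green circles replicates 1 and 2 and purple triangles replicates 3 and 4. The medians run from -0.46 for tip cell genes to 0.41 for fibroblast markers.

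Barrier and calcium genes chosen before the data were examined showed mostly lower means, and none passed on its own. The tight junction list had a median of -0.18 over 20 members (camera adjusted p = 0.0340, adjusted p = 0.519 with an estimated correlation), and Esam was its only member that fell with the batch term. Its median was -0.15 in replicates 1 and 2, where it was not called (camera adjusted p = 0.141), and -0.21 in replicates 3 and 4, where it was. Adjusted over the list alone, 8 fell and 2 rose with the batch term, and 0 passed in the planned comparison. Ocln, which encodes occludin, was at 22.7 ± 0.563 FPKM in wild type and 18.6 ± 1.49 FPKM in the libraries labelled Cavb3 knockout (SD, n = 4 each; log2 fold change -0.28, limma adjusted p = 0.0799 with the batch term). Pecam1 (-0.30, adjusted p = 0.0660) and Itpr1, an IP3 receptor of the calcium store (-0.29, adjusted p = 0.0960), also had every library labelled Cavb3 knockout below every wild type library, as did Mylk (-0.17) and Abcb1a (-0.14). Cldn5, which encodes the tight junction protein claudin-5, was at 62.4 ± 32.3 and 34.5 ± 24.7 FPKM (log2 fold change -0.99). Its 95% confidence interval was -2.31 to 0.32 in the planned fit. With the batch term it was -1.58 to -0.41 (limma adjusted p = 0.0976). The remaining values follow, with the limma adjusted p of the batch-term fit in brackets. They were -0.30 for Tjp1 (0.0715), -0.18 for Cdh5 (0.241), -0.40 for the glucose transporter Slc2a1 (0.0886) and -0.29 for Plvap (0.137). Itpr3 was at -0.35 (0.0865), Itpr2 at 0.07 (0.740), Icam1 at 0.09 (0.745) and Vcam1 at -0.39 (0.230). Mfsd2a, a lipid transporter of brain endothelium, was too low to test (0.266 ± 0.103 and 0.304 ± 0.104 FPKM). The calcium store and entry list had a median of -0.13 over 24 members (camera adjusted p = 0.0340, adjusted p = 0.519 with an estimated correlation), and lost its call with the batch term (camera adjusted p = 0.0775) and with the replicate number as a block (0.0838). It was not called in either batch alone (medians -0.10 and -0.09, camera adjusted p = 0.0937 and 0.263). Adjusted over the list alone, 4 of its members fell and 1 rose with the batch term, and 0 passed in the planned comparison. Transporters of the blood-brain barrier (median -0.06, 23 members) and adherens junction genes (-0.17, 16 members) were not called.

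Markers of other cells that such a culture could hold were mostly near the detection limit. Of 12 cell type lists, 4 had at least 5 tested members. The list of fibroblast and meningeal markers was called higher (median 0.41, 7 of 23 genes tested, camera adjusted p = 0.00138, adjusted p = 0.519 with an estimated correlation), and Twist1 was its only member that rose with the batch term. In replicates 1 and 2 its median was 0.76, and in replicates 3 and 4, where it was not called, 0.28 (camera adjusted p = 0.0747). Adjusted over the list alone, Twist1 rose in the planned comparison and with the batch term. Arterial markers were called lower (median -0.22, 7 of 16 tested, camera adjusted p = 0.0496, adjusted p = 0.519 with an estimated correlation), a call lost with the replicate number as a block (adjusted p = 0.141) and with the batch term (adjusted p = 0.117). It was also lost in each batch alone (medians -0.22 and -0.15, adjusted p of 0.199 and 0.0696). Adjusted over the list alone, 1 arterial marker, Efnb2, fell in the planned comparison and 2 fell with the batch term. Venous markers (median -0.19, 10 of 14 tested) were called lower with the batch term (camera adjusted p = 0.0476, adjusted p = 0.453 with an estimated correlation) and in replicates 3 and 4 alone (0.0114), not in the planned comparison nor with the replicate number as a block (0.0502), and fenestrated endothelial markers (median -0.23, 12 of 16 tested) were not called. The summed FPKM of choroid plexus and ependymal markers was 51.3 ± 11.02 in wild type and 136 ± 51.8 in the libraries labelled Cavb3 knockout (SD, n = 4 each; two-sided exact permutation p = 0.0286, 0.186 after adjustment over 13 marker sums), most of it from Krt19 and the water channel Aqp1. Of the 8 sums of cells other than endothelium, 4 were higher, 2 of them in both batches, and 4 were lower in both batches. The log2 differences of the lower sums were -0.47 for mural cells, -0.19 for microglia and macrophages, -0.16 for the oligodendrocyte lineage and -0.55 for neurons. The largest members of these sums were Mcam, Laptm5, Cnp and Nrgn, with means of 35.8, 29.6, 10.8 and 32.8 FPKM over the 8 libraries. Mcam is also in the tip cell list. With 1 gene holding much of each sum, these falls do not show fewer cells of those types. The remaining sums, higher in replicates 1 and 2 and lower in replicates 3 and 4, differed by 0.04 for astrocytes and 0.52 for lymphocytes and other blood cells. None of the 13 sums passed after adjustment (exact permutation adjusted p of 0.186 or more). The smallest p that 70 splits can give is 0.0286, so a sum could pass only if most of the 13 reached it. Not passing therefore says little about these sums. The sum of the endothelial identity genes was 3849 ± 470 and 3183 ± 249 FPKM (exact permutation p = 0.0571, adjusted 0.186).

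Calls close to Cacnb3 were also counted, since a targeted allele can carry flanking sequence from another strain. None of the 142 other tested genes within 10 Mb passed in the planned comparison, nor did any of the remaining 11722 tested genes, among which Cacnb3 itself was counted. With the batch term, 3 of the 142 and 72 of the 11722 passed (two-sided Fisher's exact p = 0.0608, with 0.0309 for 5 Mb and 0.205 for 20 Mb). The 3 were Acvrl1, Dhh, a hedgehog ligand (-0.51 ± 0.08 SE), and Snora2b, a small nucleolar RNA (0.50 ± 0.08) that lies within Kansl2 and whose reads may be shared with that gene. At an unadjusted p under 0.05 with the batch term, genes within 10 Mb were not enriched, at 16.9% against 19.2% of the others. The two-sided Fisher's exact p was 0.591, with 0.325 for 5 Mb and 0.514 for 20 Mb. Of the 60 genes named by the rule, 19 have exons that overlap those of another annotated gene, among them Atp1b1, Pkd1, Pfkp, Stab1, Dhh and Acvrl1 with a tested gene, and Angpt2 lies inside Mcph1 on the opposite strand. Whether counting used strand is not given in the sources used here, so reads of such pairs could not be assigned with certainty.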

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

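The test of the difference between batches was added after the batches had been seen, the tests of why Cacnb3 was not lower were chosen after its values were known, and the search for single values far from their group was planned.

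The log2 difference of Cacnb3 between the labelled genotypes was -0.63 in replicates 1 and 2 and 0.60 in replicates 3 and 4, higher by 1.23 in the latter. The limma interaction had an unadjusted p of 4.4e-04, which drew attention to it, and an adjusted p of 0.335 over all genes. Too few reads to see a loss is argued against, since the lowest library labelled Cavb3 knockout held 167 recovered Cacnb3 reads. Exchanged labels in replicates 3 and 4 would turn the 2 batches' fold changes against each other. Across tested genes they correlated at 0.234 as labelled, below the 0.332 in size reached by another of the 9 pairs of splits. With those labels exchanged, the batch-term fit called 0 genes, against 75 as labelled. Of the 32 endothelial identity genes, 19 shared a direction with labels exchanged, against all 32 as labelled. That list was picked for its small p under the labels as given, so its count cannot weigh against an exchange. Gm21887 and Gm47283, described next, had layouts that go with an exchange. They were found by a search for such reversals or picked after their values were seen, so they cannot decide it. Since the correlation as labelled was not the largest in size, an exchange stays open. A transcript kept by the targeted allele also stays open, because gene totals (ratio 0.888) hold no exon or junction, and so does a true difference between batches in Cavβ3 expression.

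Gm21887 on the X chromosome (170009659 to 170019281) had the only interaction of genotype and batch past limma's adjusted threshold (difference of log2 fold changes 6.43, adjusted p = 4.4e-06). It stood at 18.3, 19.6, 0 and 0 FPKM in wild type replicates 1 to 4 and at 4.32, 5.07, 22.9 and 24.0 FPKM in the libraries labelled Cavb3 knockout. Gm47283, picked after its values were seen, had the same layout with 0 FPKM in wild type replicates 3 and 4 (difference 3.88, limma adjusted p = 0.0782). Both are provisional gene models at the ends of the X and Y chromosomes whose reads can be shared with near copies, so their levels are uncertain.

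Abcb1a, an efflux transporter of the barrier, was at 35.4 FPKM in replicate 2 labelled Cavb3 knockout, while the other 3 libraries of that group lay between 39.4 and 39.7 FPKM. It was the only value so far from its group among 154 groups of 4 checked, a share of 0.649%, where chance gives about 5%.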

How the results depend on the processing

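All fits with the library batch, with either batch alone, with limma-voom or with the GC trend removed, and all alternatives of the batch-term count, were chosen after the data had been seen, while the other alternatives were planned.

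The planned count of 0 genes stayed 0 under every alternative planned before the data were examined and with limma-voom, GC removal and replicates 1 and 2 alone, but was 75 with the batch term and 6 with replicates 3 and 4 alone. With the replicate number as a block it was 0 (1915 genes at an unadjusted p under 0.05). Apart from the calls named in the report, the replicate block changed no camera call of a list. In the sample structure, the share of the first principal component lay between 62.6% and 66.8% with other gene sets. Cause was not tested for any change listed here unless stated.

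The estimate for Cacnb3 changed sign, and passed no test, at 0.0345 with quantile normalization, 0.0134 with median centring, 0.0212 with array weights, 0.0437 with a pseudocount of 0.1, 0.12 with limma-voom, 0.0200 with GC removal and 0.60 in replicates 3 and 4 alone. Leaving out 1 library gave -0.22 to 0.18, positive without wild type replicate 1 or 2. The limma adjusted p ranged from 0.186 to 1.00 over the alternatives. The count of called pathway lists, 16 as reported, was 0 with an estimated correlation and 0 with fry, and 11 to 17 otherwise. The count of called cell type lists, 2 as reported, was 0 with a filter at an FPKM of 5, with an estimated correlation and with fry. It was 1 with array weights, the replicate block and either batch alone (venous markers in replicates 3 and 4), and 1 to 2 without 1 library. Calls within 10 Mb of Cacnb3 were 3 with the batch term. At an unadjusted p under 0.05 in the planned fit they were 9, or 6.34%, against 5.44% of the other tested genes.

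For genes changed with the library batch as a term, the count of 75 became 0 without a filter (33196 genes tested), 193 at an FPKM of 5 (7227 tested), 1 without trend, 948 with array weights, 191 with limma-voom, 168 with GC removal, 0 with the replicate block and 0 without the batch term. It was 0 at an adjusted p of 0.01, 577 at 0.1 and 6 with an absolute log2 fold change of at least 1. Leaving out 1 library gave 0 to 322. Without replicate 4 labelled Cavb3 knockout it was 80, and leaving out any of the 4 wild type libraries or replicate 1 or 2 of the other group gave 0. The 75 genes kept their direction wherever they were tested. Of all calls, 31 of 75 were higher, against 38 of 68 with quantile normalization and 45 of 90 with median centring, which moved the median of all genes from -0.02 to 0.00 and 0.01.

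Over all alternatives, named genes gave 683 values with the same direction and side of the threshold and 453 with the same direction but short of it, and called lists gave 327 and 102. Besides Cacnb3, signs changed for Itpr2 (-0.0117 without wild type replicate 3 and -0.0248 to 0.172 over all libraries left out in turn), the median of ribosomal proteins (-0.0166 without replicate 2 labelled Cavb3 knockout, to 0.101) and that of sterol synthesis genes (-0.05 without that same library), none of them called there. Depth limits genes such as Cacnb3 with 102 to 369 reads more than abundant ones.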

Other observations

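The tests of the batches, of GC content, of endothelial share and of other cell types, and the splits for the planned gene count, for the smallest list p and for the list count with the batch term, were chosen after results had been seen, while the splits for the planned list count and for the batch-term gene count and the test of a shared axis were fixed before theirs.

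The library batches differed in genes of vessel growth and in early response genes, among others. Genes in this paragraph other than Angpt2 and Cav1 were picked after their values were seen. Apln, the tip cell ligand apelin, was at 1063 ± 350.0 FPKM in replicates 1 and 2 and 441 ± 204 FPKM in replicates 3 and 4 (SD, n = 4 each; log2 difference -1.36 ± 0.25 SE, limma adjusted p = 0.00471). Ccnd1, which encodes cyclin D1 (-2.33 ± 0.37), Cd93 (-1.49 ± 0.19), Tgfb2 (-1.38 ± 0.16), Angpt2 (-0.56 ± 0.08) and Cav1 (-0.75 ± 0.10) fell likewise in replicates 3 and 4. Acta2, smooth muscle actin, fell from 14.1 ± 7.002 to 1.08 ± 0.364 FPKM (n = 4 each; limma log2 difference -2.74, adjusted p = 7.9e-04). Fos, an immediate early gene, rose from 188 ± 126 to 534 ± 123 FPKM (n = 4 each; limma log2 difference 1.66, adjusted p = 0.0110), and the list of 30 early response genes was called higher (median 0.48, camera adjusted p = 0.00228). Camera also called tip cell genes (-0.54), sterol synthesis genes (-0.35), matrix proteases (-0.39) and cell cycle genes (0.18) between the batches. Rspo3, a secreted Wnt activator, rose both in replicates 3 and 4 (1.63 ± 0.14 SE) and in the libraries labelled Cavb3 knockout (1.16 ± 0.14, limma adjusted p = 0.0404 with the batch term).

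The distance between the batches is not a matter of sex-linked genes alone, since 45.7% of tested autosomal genes passed between them. A difference in depth is argued against as well, with 2 libraries of replicates 3 and 4 inside the depth range of replicates 1 and 2, and so is a trend with GC content, since 5460 genes passed after its removal against 5419 before. Replicates 1 and 2 held Y-linked and Xist reads, while replicates 3 and 4 held Xist reads and no read of the Y-linked genes checked. The sex make-up of the cells therefore differed between the batches. As causes of the distance, culture, sex of the animals and preparation date cannot be told apart from each other. No biological explanation was tested because the design names no such group.

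Endothelial identity genes were lower in the libraries labelled Cavb3 knockout, and a trend with GC content is argued against, since their median of -0.28 was -0.26 after its removal; the list was called at the preset correlation before and after, and with an estimated correlation neither before (adjusted p = 0.519) nor after (0.381). Cells of 8 other fixed types in those libraries stay open: the 8 lists' medians lay between 0.00528 and 0.497 FPKM there, but the choroid plexus and ependymal sum and the fibroblast sum were higher in both batches (a hand-picked list of abundant transcripts, chosen after values were seen, was dropped in favour of these fixed lists). The choroid plexus and ependymal sum rose through Krt19 and Aqp1. Of its 17 members, 13 had means under 1 FPKM in those libraries, among them Ttr (0.0260) and Kl (0.0176). That sum therefore does not show choroid plexus or ependymal cells. In replicates 3 and 4 the fibroblast sum was 76.9 and 46.9 FPKM with the knockout label and 42.3 and 49.4 FPKM in wild type. Its higher mean there thus rests on replicate 3. Of its 23 members, 15 had means under 1 FPKM in the libraries labelled Cavb3 knockout. A lower share of endothelial cells also stays open: a first criterion, 1 sum of markers lower and 1 higher at an exact permutation p of 0.05, was not met, and the spread of the 8 sums gave a one-sided exact permutation p of 0.0286 that became 0.171 without the choroid plexus and ependymal list, so the test does not decide. The smallest camera p over all lists, used since this list was picked for having the smallest p, was 6.2e-12 and was reached by 3 of the 35 splits (2.7e-20 in the highest other), so chance is not excluded, although the list's own p was smallest in the real split. Loss of Cavβ3 remains open with these, given that Cacnb3 did not separate the labels.

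The counts of calls were set against other splits of the libraries. A count of 0 genes is reached by any split (35 of 35), so that comparison says nothing about chance. Of the 35 splits into 4 and 4, the one along the batches called 4738 genes and the others 0, which points to the structure of the samples. For lists, 1 of 35 splits, the real one, reached 18 called lists, with 17 in the highest other and a median of 6.5. That share is under 0.05, but by a margin of 1 list and only over splits that ignore the batches, so chance is not excluded. With the batch term the real split called 17 lists and so did another, 2 of the 18 splits balanced within batches, so the real one does not stand out there, and 18 splits are too few for a share under 0.05. Unlabelled splits call many lists at the preset correlation. Of the same 18 splits 1, the real one, reached 75 genes with the batch term and the highest other reached 0, again with too few splits for a share under 0.05. In the 8 of 35 splits that part all pairs of replicate numbers, the real one alone reached 18 lists, and 8 are too few as well.

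A hypothesis was that the labelled genotypes and the batches differ along 1 axis of culture state, as tip cell genes were lower in both (19 of 23). Across tested genes, genotype and batch differences taken from disjoint libraries correlated at 0.165 and 0.448. The first lies between the bounds set for and against a shared axis and the second above the upper one, while both had to pass the same bound, so the question stays open. Genes are not independent replicates.

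Aqp1 and other genes often seen in epithelial or mesenchymal cells, picked after their values were seen, varied among the libraries labelled Cavb3 knockout. Aqp1 was at 51.1, 127, 29.0 and 15.3 FPKM there and at 12.5 to 15.3 FPKM in wild type. Dsp, a desmosome protein, was at 5.79 ± 1.01 and 13.8 ± 3.98 FPKM, Lgals3 at 23.5 ± 2.59 and 42.9 ± 8.23 FPKM and Igfbp6 at 20.47 ± 2.91 and 46.7 ± 18.1 FPKM (SD, n = 4 each, wild type first). Their limma adjusted p-values with the batch term were 0.0572, 0.0609 and 0.0886, so none passed. Only genes with higher means were picked here, and other genes of such cells were not higher. Krt18, an epithelial keratin, was at 0.628 ± 0.242 and 0.625 ± 0.140 FPKM. Of mesenchymal genes, Acta2 was at 10.4 ± 10.9 and 4.83 ± 4.87 FPKM and Tagln at 1.88 ± 1.45 and 0.976 ± 0.322 FPKM (SD, n = 4 each, wild type first).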
